A study of Mus musculus with 2 samples.

How the data were processed

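The series held 2 DNase-seq libraries from the cerebellum of male B6CASTF1/J mice, the first-generation cross of C57BL/6J and CAST/EiJ, aged 18 to 20 months per the labels. DNase-seq marks stretches of chromatin that the nuclease DNase I reaches and digests. The labels gave each library its own biosample and its own biological replicate number, and they gave both the same donor identifier, so the labels left open whether the libraries came from separate mice. Both libraries formed 1 group, and replicate 1 and replicate 2 follow the labels' numbers. With 1 group of 2 libraries, no test between conditions could be made, and all values describe these libraries.

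For each library, 4 kinds of region were used: a smaller and a larger list of peaks, footprints, and segments with a false discovery rate. Per the file headers' listings, all were made from 1 alignment file per library on the mm10 assembly, and the aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. The signal of a peak is the height that the authors deposited with it. Every deposited height was a whole multiple of 1 step per library, 0.00643 in replicate 1 and 0.00542 in replicate 2, to within 0.02 of a step or, where that was more, a fraction of 1e-05 of the height, so the heights had been scaled by a constant per library, which the sources used here do not give. The sequencing depth was not given either. The median height corresponded to 184 steps in replicate 1 and 272 in replicate 2. What 1 step stands for is unknown, so no depth was computed from it. Every peak of the deposited smaller list held a position with an FDR of at most 0.000994 in replicate 1 and 0.000992 in replicate 2, and every peak of the larger list held one of at most 0.0499 and 0.0500. Every deposited footprint carried the score 0.01, so footprints could not be ranked. The smaller list was used throughout, and the larger list only where it is named. Signal tracks and alignments were not used here.

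Peaks of the libraries counted as shared when they overlapped by at least 1 bp. The chance level came from 20 seeded shuffles of the peaks within their chromosomes, outside assembly gaps. Heights were compared over pairs of shared peaks by Spearman's correlation and, on the log2 scale, Pearson's. These are correlations across regions, which are not independent replicates, so no p-value was computed. Gene positions came from the GENCODE M21 basic annotation of GRCm38, the assembly that mm10 names, and sequence from the GRCm38 reference of C57BL/6J. A peak within 1000 bp of a transcription start site counted as a promoter peak, then exon, intron and intergenic classes were assigned in that order, and all peaks outside the promoter class counted as distal. Per gene, the promoter height was that of the highest peak within 1000 bp of any of its transcription start sites, or 0, and distal peaks were counted within the gene and 20 kb on either side, per 100 kb searched, where a peak of the other library overlapped them. A promoter peak of this kind can belong to a neighbouring or divergent gene.

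Before the data were examined, 20 gene lists were fixed from textbook knowledge. They were markers of granule neurons, Purkinje cells, inhibitory interneurons, unipolar brush cells, astrocytes and Bergmann glia, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, meningeal and choroid plexus cells, forebrain neurons, liver, skeletal muscle, lymphocytes and erythroid cells, and genes of midbrain-hindbrain patterning, housekeeping, the immediate early response, the circadian clock, and glial reactivity and senescence. Of 281 entries, 278 matched a protein-coding gene; Trac, Ighm and Clec7a did not. Each list's share of genes with a promoter peak in both libraries, its median promoter height and its median number of distal peaks were placed among 10000 random lists of the same number of genes out of 21911 protein-coding genes. A list was called higher or lower outside the 2.5 to 97.5 percentiles. Genes are not replicates, so a percentile is no p-value.

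The genes named were fixed by rule at the same stage. They were the 3 members of each list with the highest mean promoter height, and the first 2 in list order with no promoter peak in either library. Genome-wide, the rule took the 10 distal peaks over 2500 bp from any transcription start site with the highest mean rank, the 10 genes with the most distal peaks per 100 kb among those with at least 10 in each library, and the 5 highest peaks of each library that no peak of the other overlapped. Some genes that the rule takes are not reported here, and they stay in the counts of their lists. Any other gene or site was named after its values were seen.

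Matches to 23 fixed consensus sequences were counted on both strands in peak sequence. The density inside footprints was divided by that in the rest of the peak sequence, with an exact Clopper-Pearson 95% interval for the ratio in each library. Each ratio was also divided by that of up to 10 shuffled forms of the same letters. Its interval was divided by the same value, so the error of the shuffled ratio is not in it. Intervals of shares are Wilson 95% intervals. All intervals cover counting error only.

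The alternatives tried were transcription start site windows of 250 and 2500 bp, a reciprocal overlap of 50%, peaks at or above each library's median height, equal numbers of the highest peaks, the larger list, random lists matched on promoter GC content or gene length in 20 bins, flanks of 5 and 100 kb, autosomes alone, chromosome lengths without gaps, promoter peaks per gene, footprints widened by 5 bp, the 50 bp beside footprints as background, distal footprints, peaks in the same height bins and each library alone. Chosen after seeing the data were the larger list for gene lists, overlap with FDR segments for peaks of 1 library, heights doubled on autosomes against the X chromosome, gene families by symbol, height ratios of kinds of sequence and of gene lists matched on GC content, and a search for near-identical sequence.

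The peak overlap, the gene list percentiles and the motif densities were tested on simulated data, and the other statistics were not. For the peak overlap, with 50000 peaks, planted shares of 40% and 80% came back as 40.4% and 80.0%. For the gene lists, 3.5% of 200 unchanged lists fell outside the range. So did 100% of 200 lists in which all values below 1 were set to 1 and then all were raised 4-fold. This setting left no closed gene in a raised list, so it does not show how often lists with closed genes would be found. Only the median was simulated, and no lowered lists were. For the motif density, 100 sets with a planted ratio of 5 gave a median of 4.85, and 95% of the intervals held the planted value. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, bedtools 2.31.1 and blastn 2.17.0.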

Results

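Accessible chromatin was mapped in adult mouse cerebellum, the part of the brain in which granule neurons outnumber all other cells. The libraries, replicates 1 and 2 of 1 group, held 82045 and 100059 peaks in the smaller list, with median widths of 200 and 180 bp, and covered 17.0 and 18.7 Mb. The larger list held 118306 and 154971 peaks. The median peak height was 1.18 in replicate 1 and 1.47 in replicate 2, in the deposited units, and the highest peaks reached 73.0 and 78.8. These highest peaks, at CT010467.1 and at Dynlt1b on chromosome 17, had 1 and 3 near-identical copies elsewhere in the assembly, so their heights are uncertain. The sequencing depth is unknown. The labels set no condition against another, so the comparisons are between the libraries, between gene groups within them, and between their peaks and random positions.

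Most open sites were found in both libraries, and the highest ones nearly always were. A peak of replicate 2 overlapped 89.7% of the peaks of replicate 1 (95% interval 89.5 to 89.9), and a peak of replicate 1 overlapped 74.0% of those of replicate 2 (73.8 to 74.3). Shuffled peaks gave 1.59% and 1.31%, and at most 1.63% and 1.38% in any of 20 shuffles. Among 5 groups of equal size by height, the shared part went from 66.4% in the lowest to 99.9% in the highest group of replicate 1, and from 34.2% to 98.9% in replicate 2. With equal numbers of the highest peaks, the shares were 82.7% and 83.1%.

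Across 72410 pairs of shared peaks, heights had a Spearman correlation of 0.951 and a Pearson correlation of 0.958 on the log2 scale. Pairs of peaks are regions, not independent replicates. Heights in replicate 2 were above those in replicate 1 by a median of 0.65 on the log2 scale (SD over pairs 0.43), and 97.55% of pairs lay within 2-fold of that median ratio. The shift was not equal over the genome. It was 0.74 at 22269 promoter pairs, 0.66 in exons, 0.58 at 28133 intron pairs and 0.60 in intergenic sequence. The promoter shift exceeded that of introns by 0.16 (0.15 to 0.17 over 200 resamplings of pairs), and by 0.03 once peaks were matched on GC content and height. The matched value covers 15413 of the 22269 promoter pairs, those in bins with at least 20 pairs of each class.

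**Figure D1:**
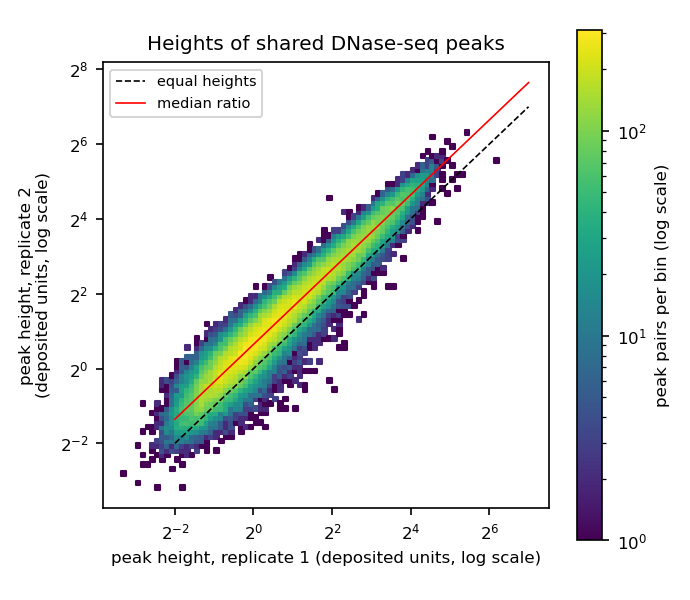
Peak height in replicate 1 (x axis) against replicate 2 (y axis), in deposited units on log scales, for 72410 pairs of shared peaks; colour gives the number of pairs per square. The cloud follows the line of the median log2 ratio, 0.65, above the line of equal heights.

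Promoters took up a larger part of the open chromatin than of the genome. Promoter peaks made up 30.4% of the peaks of replicate 1 and 30.2% of those of replicate 2, against 4.96% and 4.90% of shuffled peaks, which is 6.13-fold and 6.15-fold more. Introns held 39.3% and 39.6%, exons 6.53% and 7.06%, and intergenic sequence 23.8% and 23.2%, the last against 49.8% of shuffled peaks in each library. Promoter peaks were also the highest class, with medians of 2.08 and 2.43 against 1.03 and 1.28 in introns and 0.939 and 1.20 between genes. The promoter share depends on the window: it averaged 19.4% within 250 bp of a start site. Of 21911 protein-coding genes, 57.5% had a promoter peak in both libraries.

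Granule neuron genes had open promoters and dense distal sites. All 16 markers had a promoter peak in both libraries, against a median of 56.2% in random lists (percentile 100), and their median promoter height of 10.0 lay at the 99.25 percentile. Heights are given from here on as means over both libraries ± SD, n = 2. They were not rescaled between the libraries, so the SD includes the common shift of replicate 2, a median of 0.65 on the log2 scale. A small SD can therefore mark a gene that departs from this shift. The highest were Cbln3, which encodes a cerebellin of granule neurons, at 21.7 ± 7.29 (chromosome 14, 55878913 to 55884392), the transcription factor gene Neurod1 at 19.2 ± 4.19 (chromosome 2, 79452521 to 79456751) and Il16 at 14.96 ± 1.28 (chromosome 7, 83642825 to 83745726). Their median of 15.2 distal peaks per 100 kb compared with 1.97 in random lists, the central 95% of which ranged from 0 to 4.15 (percentile 100). Neurod2 averaged 37.3, Zic2 34.9 and Neurod1 20.3 distal peaks per 100 kb, counting only peaks that the libraries shared.

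**Figure D2:**
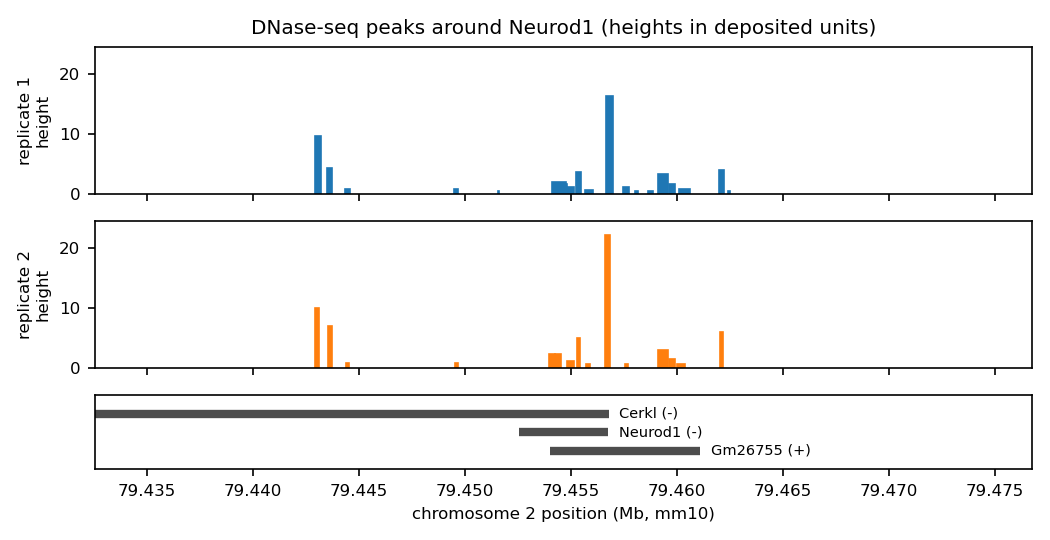
Peaks of the smaller list around Neurod1, 20 kb on either side, with position on mm10 chromosome 2 (x axis, Mb) and height in deposited units (y axis) for each library; bars span the peaks, and the lowest panel shows annotated genes with their strand. In this window of 44.23 kb, replicate 1 had 19 peaks and replicate 2 had 15.

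Markers of Purkinje cells, interneurons, unipolar brush cells, astrocytes and the oligodendrocyte lineage lay within the range of random lists for open promoters, and none exceeded it for distal peaks or height. Of 16 Purkinje cell markers, 10 had a promoter peak in both libraries (percentile 64.83). They included Itpr1, the inositol trisphosphate receptor of Purkinje cells, at 18.7 ± 8.79, Aldoc at 11.6 ± 5.78 and Lhx1 at 11.5 ± 4.86, while Pcp2 and Car8 had none. Inhibitory interneuron markers were open for 8 of 16 (percentile 26.84), with Prkcd at 2.08 ± 0.801, Nxph1 at 1.53 ± 0.522 and Lypd6 at 1.23 ± 0.252 as the highest. Gad1, which encodes an enzyme of GABA synthesis, and the glycine transporter gene Slc6a5 had no promoter peak, although the larger list held one at Gad1 in both libraries, with heights of 0.367 and 0.694. Against random lists matched on promoter GC content, the interneuron list fell below the range (percentile 1.66). Of 8 unipolar brush cell markers, 5 were open (percentile 60.26), with Plcb1 at 7.19 ± 3.54 and Calb2 at 5.27 ± 1.02, and none at Lmx1a and Samd3.

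Astrocyte and Bergmann glia markers were open for 8 of 14 (percentile 48.58). Glul, the gene of glutamine synthetase, stood at 11.2 ± 5.24, Slc1a2 at 3.41 ± 1.42 and Fabp7 at 2.19 ± 1.1003, and Gdf10 and Gfap had no promoter peak. The larger list held one at Gdf10 in both libraries, with heights of 0.264 and 0.396, and in replicate 2 alone at Car8 (0.201), Gpr17 (0.239), Emx2 (0.260) and Pax2 (0.548). Oligodendrocyte markers were open for 6 of 15 (percentile 9.15), with Mbp, the gene of myelin basic protein, at 4.08 ± 2.21, Cnp at 1.47 ± 0.718 and Myrf at 1.40 ± 0.601, and none at Mobp. Oligodendrocyte precursor markers were open for 5 of 10 (percentile 31.86), the highest being Lhfpl3 at 1.07 ± 0.512, Pdgfra at 0.825 ± 0.412 and Sox6 at 0.691 ± 0.204, and none at Cspg4 and Gpr17. With only peaks at or above the median height, called the higher peaks from here on, the interneuron, oligodendrocyte and precursor lists fell to percentiles of 0, 0.02 and 0.06. The glial reactivity and senescence list had 5 of 14 genes open (percentile 5.35), with Il6 at 5.77 ± 2.91, Cdkn1a at 3.35 ± 1.65 and Apoe at 0.891 ± 0.305, and none at Il1b and Serpina3n; that list fell to 0.29 with the higher peaks.

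**Figure D3:**
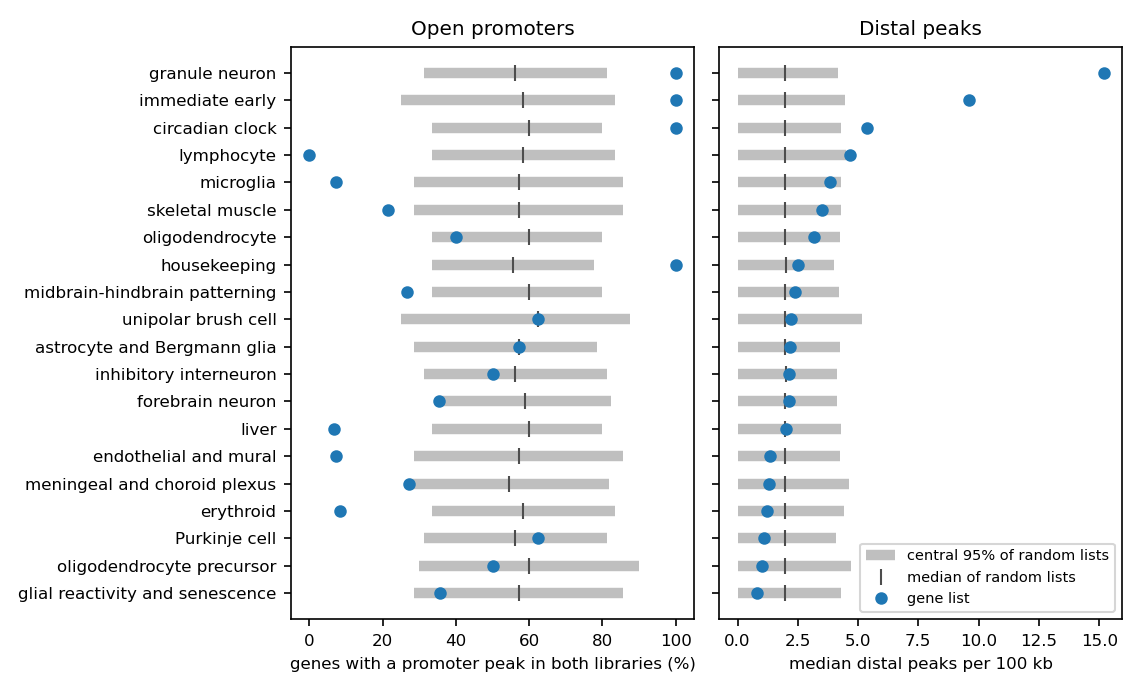
For each of the 20 gene lists, the left panel gives the percentage of genes with a promoter peak in both libraries and the right panel the median number of distal peaks per 100 kb. Dots are the lists, grey bars the central 95% of 10000 random lists and ticks their medians; granule neuron genes stand at 100% and 15.2.

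Microglia markers and those of endothelial and mural cells had fewer open promoters than random lists. Microglia markers were open for 1 of 14 (percentile 0.00). C1qc had a peak in replicate 1 alone, at 0.379 ± 0.537. Csf1r and Cx3cr1 had no promoter peak, and 1 and 14 distal peaks in each library. In whole tissue, a missing peak does not show that a promoter was closed in a cell type that forms a small part of it. Median distal peaks per 100 kb were within the range for microglia markers (3.83, percentile 94.81) and for endothelial and mural markers (1.36, percentile 24.72). Endothelial and mural markers were open for 1 of 14 (percentile 0.00), with Kcnj8 at 0.520 ± 0.254, Pdgfrb at 0.249 ± 0.353 and Erg at 0.230 ± 0.326, and none at Cldn5 and Pecam1. Meningeal and choroid plexus markers, at 3 of 11 (percentile 2.52), lay just within the range. Their highest were Col1a1 at 5.87 ± 3.16, Foxj1 at 3.81 ± 1.25 and Otx2 at 1.21 ± 0.096, and Dcn and Lum had none. This list fell below the range with a window of 250 bp (percentile 0.93) and with the higher peaks (1.74).

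Liver markers were open for 1 of 15 (percentile 0.00), namely Apob at 1.23 ± 0.509, and the albumin gene Alb and Apoa1 had no peak. Lymphocyte markers were open for 0 of 12 (percentile 0.00), including Cd3e and Cd3d, which encode chains of the T cell receptor complex. Erythroid markers were open for 1 of 12 (percentile 0.03). Klf1 had a peak in replicate 2 alone, at 0.404 ± 0.571, and there was none at the globin genes Hbb-bs and Hbb-bt. Skeletal muscle markers were open for 3 of 14 (percentile 0.40): Mylpf at 13.8 ± 2.12, Actn3 at 10.0 ± 2.07 and Tnnt3 at 1.78 ± 0.551, with none at the myosin genes Myh1 and Myh2. The muscle list lay within the range with a window of 2500 bp (percentile 40.35), and a promoter peak at these genes can belong to a neighbour.

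Most genes of the forebrain and of early midbrain-hindbrain patterning lacked a promoter peak in at least 1 library. Forebrain neuron markers were open for 6 of 17 (percentile 3.76), with Cux2 at 2.07 ± 0.233 and Lhx2 at 1.69 ± 1.01, and Emx2, a transcription factor gene of the developing forebrain, had none. Matched on promoter GC content, this list fell to percentile 0.08, and it also lay below the range with a window of 2500 bp (2.24), equal numbers of peaks (1.46), the higher peaks (0.38) and the larger list (1.81). Midbrain-hindbrain patterning genes were open for 4 of 15 (percentile 1.01). En2, an engrailed gene of the midbrain and cerebellum, reached 11.0 ± 4.29 with 21.5 distal peaks per 100 kb, Irx3 2.16 ± 1.08 and En1 0.905 ± 0.215, and Gbx2 and Pax2 had none.

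Housekeeping, immediate early and circadian clock genes were open throughout, with 18 of 18 (percentile 99.99), 12 of 12 (99.92) and 15 of 15 (99.99) promoters. Clock genes had the highest median of all lists, 19.2 (percentile 100), led by Per1 at 29.5 ± 9.52, Nr1d2 at 29.1 ± 11.2 and Dbp at 26.3 ± 8.14. Housekeeping genes had a median of 13.5 (percentile 99.98), with Ywhaz at 22.1 ± 8.79 and the ribosomal protein genes Rplp0 at 21.9 ± 0.104 and Rpl13a at 21.1 ± 3.74. Immediate early genes, which neuronal activity induces, had a median of 8.76 (percentile 96.97), with Jun at 26.6 ± 9.68, Dusp1 at 18.6 ± 7.71 and Egr1 at 16.4 ± 5.19. Distal peaks were dense near immediate early genes (median 9.59 per 100 kb, percentile 100) and clock genes (5.36, percentile 99.77), and not near housekeeping genes (2.51, percentile 77.38). Matched on promoter GC content, the open share of immediate early genes lay within the range (percentile 95.84), and their height passed it in replicate 1 alone (97.59) and with a window of 2500 bp (99.14).

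Among the other lists, only lymphocyte genes exceeded the range for distal peaks (4.65 per 100 kb, percentile 98.01), and they fell to percentile 20.91 with a flank of 5 kb, so peaks of neighbouring genes can enter this count. Housekeeping genes passed the range with a flank of 5 kb (99.64), microglia markers with 100 kb (98.64) and oligodendrocyte markers with the higher peaks (98.69). Apart from the granule, clock and housekeeping lists, no list exceeded the range in median promoter height. The lower limit of the range was 0 for every list, both for height and for distal peaks, so a list could not fall below it. Against random lists matched on promoter GC content, where 8 of the 20 limits lay above 0, the interneuron (1.72), forebrain (0.27) and midbrain-hindbrain (0.47) lists fell below it. The medians were 2.96 for Purkinje cells, 1.096 for unipolar brush cells, 0.756 for astrocytes, 0.641 for interneurons and 0.401 for oligodendrocytes.

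Distal peaks were densest at Barhl2 (chromosome 5, 106452523 to 106458166), a homeobox gene, with 50.4 per 100 kb, the clock repressor gene Nr1d1 with 45.4 and Neurod2 with 37.3. They were followed by Thra, a thyroid hormone receptor gene, at 35.1, Zic2 at 34.9, Nptx1 at 34.7, Zic5 at 33.8, Aurkb at 32.6, B4galt5 at 31.4 and Mcts2 at 29.3. These are means over both libraries of peaks that the libraries shared, so the counts of the libraries were close by construction. Their SD, at most 2.07 (Thra), is therefore no measure of how far the libraries differ. The median gene had 1.99. Nr1d1 and Thra overlap on chromosome 11, and Zic2 and Zic5 lie side by side on chromosome 14, so these pairs share peaks. The search took in 20 kb on either side. For a short gene such as Mcts2 (chromosome 2, 152687035 to 152687946), most of it is flank, and peaks of neighbouring genes can enter the count.

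The first distal peak by mean rank lay in an intron of Vps37c (chromosome 19, 10709481 to 10709680), with heights of 24.8 and 40.01 in replicates 1 and 2. Next came an intergenic peak on chromosome 6 near Igf2bp3 (49236421 to 49236620; 36.3 and 36.2), a peak in an exon of Lars2 on chromosome 9 (123461901 to 123462100; 39.1 and 35.8) and an intron of Uggt2 on chromosome 14 (119007481 to 119007720; 20.5 and 43.1). The others lay 6237 bp from Trappc9 (21.4 and 35.9), in an intron of Gm20388 (20.0 and 33.2), between genes on chromosome 3 at 5860361 to 5860530 (35.2 and 29.2), in an exon of Mamstr (19.05 and 34.5), 3422 bp from Tle2 (19.9 and 31.3) and in an intron of Chd8 (18.8 and 31.3). The peaks on chromosomes 6, 9 and 3 had 2, 4 and 15 near-identical copies elsewhere in the assembly, so their heights are uncertain.

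The single X chromosome of these males carried fewer peaks than any autosome. It had 13.1 and 14.7 peaks per Mb in replicates 1 and 2, against autosomal medians of 32.8 and 40.6, a ratio of 0.3999 and 0.363. The lowest autosome, chromosome 3, had 23.2 and 27.6, and the highest, chromosome 11, had 50.4 and 62.3. Peaks on X were also lower, with median heights of 0.720 and 0.976 against 1.18 and 1.48. Per protein-coding gene, X had 0.916 and 1.05 promoter peaks against 1.20 and 1.42, and the ratio averaged 0.751. The Y chromosome had 20 and 47 peaks.

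Footprints, the short protected stretches within open chromatin, were found in most peaks. The libraries held 311467 and 386056 of them, with medians of 10 and 11 bp, and 74.8% and 69.9% lay in peaks of the smaller list. Distal peaks held a footprint more often than promoter peaks did: 89.7% against 80.5% in replicate 1 and 91.6% against 81.9% in replicate 2. Within the same height bins the gap was wider, 92.0% against 74.9% and 91.8% against 73.9%. Over all heights, promoter peaks averaged 3.29 footprints against 2.58 in distal peaks, and 2.90 against 2.48. They averaged fewer than distal peaks in the lower 5 of 10 height bins of replicate 1 and in the lower 7 of replicate 2. In the lowest of 10 height bins, 36.1% and 49.5% of promoter peaks held one, and in the highest bin 99.8% and 99.95%. Of the footprints in shared peaks, 72.7% and 64.8% were overlapped by a footprint of the other library. No chance level was computed for this overlap, so part of it can be chance. Within peaks, footprints covered 3315 kb and the rest of the sequence 13643 kb in replicate 1, and 4271 and 14461 kb in replicate 2.

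Footprints held more matches than the rest of the peak sequence for 12 of the 23 consensus sequences, in both libraries. Over all peaks, the ratio was highest for NRF1, a regulator of housekeeping and mitochondrial genes, at 89.6 (95% interval 55.2 to 155) and 68.3 (43.1 to 115), and for the insulator protein CTCF at 39.6 (36.1 to 43.6) and 90.9 (79.0 to 105). CTCF differed between the libraries beyond the intervals, with 1.39 and 1.29 matches per kb inside footprints and 0.0352 and 0.0142 outside. CRE followed at 22.5 and 31.1, NFI at 15.2 and 21.4, SP_KLF at 9.35 and 10.8, RFX at 9.04 and 9.25, EGR at 6.47 and 6.08, YY1 at 6.69 and 4.98, ETS at 4.21 and 3.97 and NFY at 1.92 and 1.74. Among factors of the granule lineage, the NEUROD_ATOH sequence reached 4.64 (4.50 to 4.78) and 3.96 (3.85 to 4.08), with 9222 and 9602 matches in footprints, and ZIC 2.11 (2.05 to 2.18) and 2.17 (2.11 to 2.23). Over shuffled forms, all 12 stayed denser in both libraries, by intervals that take the shuffled ratio as exact. SP_KLF and ZIC averaged 1.51 and 1.43 there, EGR 2.85, CTCF 31.1 and NRF1 49.7, while NEUROD_ATOH rose to 5.77 and YY1 to 8.80. In distal footprints alone, NRF1 stood at 33.2 and 29.5, below CTCF at 41.6 and 98.0, while CRE fell to 10.1 and 14.9 and ETS to 1.92 and 1.54. The interval of YY1 there held 1 in both libraries, with an average of 3.06.

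For 6 consensus sequences, matches were less dense in footprints than in the rest of the peak sequence in both libraries. GATA stood at 0.418 and 0.344, PU1, the sequence of a blood lineage factor, at 0.432 and 0.524, and the homeodomain sequence HOMEO at 0.450 in each. ROR stood at 0.430 and 0.668, AP1 at 0.650 and 0.760 and TEAD at 0.814 and 0.800. Over shuffled forms, ROR, AP1 and TEAD averaged 1.05, 1.05 and 1.02, so shuffled forms of the same letters were about as sparse, and AP1 averaged 0.946 with footprints widened. HNF4 (1.32 and 1.07), REST (1.06 and 1.101), SOX (0.920 and 1.09) and MEF2 (0.806 and 0.737) had intervals that held 1 in at least 1 library, and HNF1 had 0 matches. Over shuffled forms, SOX and MEF2 averaged 1.63 and 1.60, and HNF4 and REST did not pass in both libraries. The intervals of SOX and MEF2 lay above 1 in both, but they left out the error of the shuffled ratio. That ratio can vary: for REST it was 0.257 in replicate 1 and 2.26 in replicate 2.

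**Figure D4:**
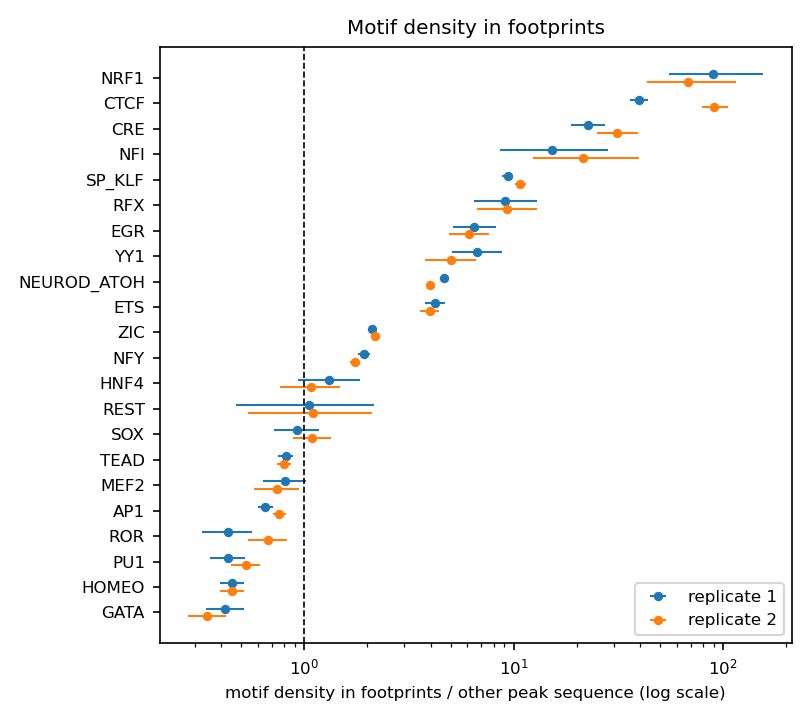
Ratio of motif density in footprints to that in the other peak sequence (x axis, log scale) for each consensus sequence with matches (y axis), over all peaks in replicate 1 and replicate 2; bars are 95% intervals for counting error. NRF1 and CTCF stand highest, and GATA lowest at 0.418 and 0.344.

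Some of these matches fell in footprints of both libraries at the named sites. At the Neurod1 promoter (chromosome 2), NEUROD_ATOH matches lay at 79456872 to 79456879 and at 79456979 to 79456985. Both were inside the peak of replicate 1 (79456641 to 79457000) and outside that of replicate 2 (79456621 to 79456860). The Il16 promoter peaks held such matches at 83735675 to 83735681 and 83735754 to 83735760. NEUROD_ATOH matches were not confined to granule neuron genes. The promoter peaks of the liver marker Apob (chromosome 12) held them at 7978735 to 7978741 and 7978746 to 7978753. The Cbln3 promoter peak held 5 footprints in each library and 0 matches of this kind. CRE matches TGACGTCA lay at the promoters of Ywhaz (chromosome 15, 36793664 to 36793671) and Dusp1 (chromosome 17, 26508608 to 26508615) and in the distal peak near Tle2 (chromosome 10, 81571732 to 81571739).

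Peaks of 1 library alone were mostly low. Replicate 1 had 8444 that no peak of replicate 2 overlapped (10.3%, 10.1 to 10.5), with a median height of 0.457 against 1.36 for shared ones, and replicate 2 had 25990 (26.0%, 25.7 to 26.2), with 0.656 against 2.15. The highest in replicate 2 lay 278 bp from the start of Bahcc1 (chromosome 11, 120232621 to 120232669; height 20.2), 154 bp from Ngdn (18.3), 33234 bp from Pum2 (14.6), in an exon of Crlf2 (13.98) and at Zfp446 (13.3). The highest in replicate 1 lay at 2010320M18Rik and Pik3r2 (10.6), 9819 bp from Tmpo (6.67), 241 bp from Ppm1l (5.49), 109 bp from Tpgs1 (5.29) and 308 bp from Ell (4.95). All 10 overlapped an FDR segment of the other library, and none overlapped its larger list. Of these, 3536 and 14845 peaks had no counterpart in the other library's larger list, and 1973 and 9027 touched no FDR segment of it. Peak calls of separate libraries were thresholded separately, and no test of single sites could be made with 2 libraries.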

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

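The tests in this part were chosen after seeing the data, although promoter peaks per gene had been fixed before as an alternative. Those of gene density for the X chromosome, of granule neuron genes after matching, and of fewer granule neurons were chosen only after related results had been seen.

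Footprints outside the larger peak list numbered 44773 in replicate 1 (14.4%) and 57776 in replicate 2 (14.97%). They stood out because the comparisons of the report used only footprints within peaks, and no control sample gave a background level. Of all footprints, 99.8% and 99.7% lay in FDR segments.

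The X chromosome had fewer and lower peaks than the autosomes in both libraries. A single copy that only lowered peak height 2-fold was argued against: X density at a height of 1 or more, over autosomal density at 2 or more, averaged 0.446, below the lowest autosomes (0.653 and 0.627). Fewer genes per Mb on X, 5.54 against 7.81, stay open: X had 0.982 promoter peaks per gene on average, above the lowest autosome in replicate 1 (0.908) and below it in replicate 2 (1.13). Both together may account for the promoter part of the pattern. X promoter peaks per gene at a height of 1 or more, over the autosomal median at 2 or more, averaged 0.800. This lay above the lowest autosome by a small margin (0.801 against 0.778 and 0.799 against 0.794) and below the autosomal median. No other heights were tried for promoter peaks, so the margin decides little. The effect of a single copy could not be tested against animals with 2 copies, since both libraries came from males.

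The height ratio of replicate 2 to replicate 1 was unequal between kinds of sequence. The gap between promoters and introns was 0.16 on the log2 scale over all pairs, and 0.033 after matching on GC content and height. The matched value covers 15413 of 22269 promoter pairs, and the unmatched gap of those pairs was not computed. The median log2 ratio was 0.41 in the lowest of 5 GC groups and 0.80 in the highest. GC content could account for the gap as far as pairs were matched. It was argued against for granule neuron genes, whose distal peaks had a median of -0.247 after matching on GC content, height and class, outside the range of random lists (-0.09 to 0.17), with 13 of 16 genes below 0, such as Zic2 at -0.40 and the overlapping genes Zic1 at -0.55 and Zic4 at -0.49, which share peaks. A different mix of cell types in the pieces of tissue cannot be told apart from other causes. At all peaks, 2 of 8 cerebellar cell type lists, granule neuron (percentile 0) and Purkinje cell (1.75), lay outside the range, as did the liver list (98.99). At distal peaks matched also on class, the Purkinje list lay within it (20.6). Fewer granule neurons alone stay open too, since 4 of the other 7 lists lay above the random median in distal peaks and none below the range. The 4 were the astrocyte (0.121), oligodendrocyte (0.204), precursor (0.075) and microglia (0.049) lists. The Purkinje (-0.061), interneuron (-0.090) and unipolar brush cell (-0.065) lists lay below the random median. All 7 lay within the range, with 3 to 8 genes each, so no conclusion is drawn from this split. The design named no biological difference between the libraries, and whether separate animals gave them is open.

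Among the 725 highest pairs, the top 1% with a mean height of at least 21.5, 7 were lower in replicate 2, while the other 718 had a median log2 ratio of 0.79. Sequence with near-identical copies elsewhere (at least 90% identity over 80% of the peak) may account for them. Such a copy was found for 6 of the 7 (85.7%), against 5 of the others (0.696%). Those 5 had log2 ratios from 0.04 to 1.67, so a copy did not go with lower heights in replicate 2 alone. The most extreme lay at CT010467.1 on chromosome 17 (39846781 to 39846900), with heights of 73.0 and 47.7, and the 7 held the distal peaks at Lars2 and on chromosomes 3 and 6 as well. The peak at Rplp0 (21.97 and 21.8) had no copy and stays unexplained. No biological explanation was tested.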

How the results depend on the processing

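Overlap with FDR segments, heights doubled on autosomes and the larger list for gene lists were chosen after seeing the data. Of 80 recomputed values that answer a comparison, 65 stayed close and 15 did not. Close means within 1.5 times for counts, within its 95% interval for the correlation and within 1 SD of the libraries for the others. These measures are unlike. The interval treats pairs of peaks as independent, so it is narrow. For the peak overlap, the SD is that between the 2 directions (89.7% and 74.0%), so it is wide. A reciprocal overlap gave 81.1% and 66.5% and the larger list 84.9% and 65.3%, and both counted as close. The cause of a move was not tested, except where a stricter list or a wider window leaves fewer or more peaks by construction. With peaks at or above the median height, the Spearman correlation was 0.925, 13 lists had fewer open promoters than random lists (7 with all peaks), the promoter share was 38.8%, the X ratio 0.264 and the number of peaks of 1 library 11785 (34434 with all). With a reciprocal overlap the correlation was 0.952. The promoter share was 19.4% with 250 bp and 37.9% with 2500 bp, against 30.3%. Against GC-matched lists, 3 lists had lower promoter heights; the count of 0 against unmatched lists was fixed by their lower limit of 0. The X ratio, 0.381 as a mean, became 0.751 per gene and 0.446 with doubled heights. Promoter peaks with a footprint fell from 81.2% to 74.4% in the same height bins. Over shuffled forms, 3 consensus sequences were less dense in footprints (6 otherwise), and AP1 (1.05), ROR (1.05), TEAD (1.02) and MEF2 (1.60) changed side. SOX (1.63) gained a call as denser there. The calls over shuffled forms take the shuffled ratio as exact. Peaks of 1 library numbered 18381 against the larger list and 11000 against FDR segments. The lymphocyte list changed side for distal peaks with a flank of 5 kb (percentile 20.9). Of the values of single lists, consensus sequences, genes and sites, 1042 kept their call, 22 gained one, 4 lost one and 29 moved. Leaving out either library moved no count of lists or consensus sequences by over 1.5 times; for means of 2 libraries, neither value can leave the spread by construction. Ranking footprints by score was not run, since the score is constant. No paired analysis was possible because the series holds 1 group. Depth is unknown, so the higher number of peaks in replicate 2 was not tested against depth.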

Other observations

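The gene families in this part were chosen after seeing the data.

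Very few genes of the sensory receptor families had a promoter peak in both libraries. Families were not matched on promoter GC content. Its median was 37.45% for Olfr, 37.55% for Vmn1r and 36.35% for Vmn2r genes, against 55.95% and 57.35% for mitochondrial and cytosolic ribosomal protein genes and 56.9% for Hox genes. Near-identical sequence was searched only for the highest pairs of peaks, so its part here is unknown. Of 1134 olfactory receptor genes (symbols starting with Olfr), 9 had a promoter peak in both libraries (0.794%), and of the vomeronasal receptor genes, 1 of 208 Vmn1r and 0 of 120 Vmn2r genes did. Of 39 Hox genes, which pattern the body axis behind the cerebellum, only Hoxc5 had one, with a mean height of 0.686. The clustered protocadherin genes, which give neurons their surface identity, were open for 27 of 56 (48.2%), the highest being Pcdhgc3 at 10.7.

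Families with general functions were open in most members. All 78 mitochondrial ribosomal protein genes had a promoter peak in both libraries, with a median height of 8.70, and 79 of 82 cytosolic ribosomal protein genes did, with a median of 11.8. Histone genes were open for 52 of 67 (77.6%; median 4.26) and genes with a Zfp symbol for 333 of 394 (84.5%; median 6.48). Over all protein-coding genes, the share was 57.5%.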
